A study of Mus musculus with 20 samples.

How the data were processed

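RNA from the central part of the left lateral liver lobe of each sample was kept in RNAlater, isolated with the RNeasy kit and labelled with biotin by the Affymetrix 3' IVT Express kit, per the labels. The data are 1 table of 17306 probe sets on 20 arrays, 5 in each of 4 groups. Per the submitters' processing notes the authors summarised the probe signals by RMA, and the deposited values are log2 RMA levels between 1.91 and 14.2. The probe sets carry Entrez gene numbers, 1 per gene, so a gene-level probe definition was used; its version, the genome build, any filter and which arrays were normalized together are not given in the sources used here. Array medians ran from 4.47 to 4.67. The values were used as deposited, with no further scaling and no filter on low values. Of the probe sets 16464 carried 1 gene symbol and were tested, 0 carried several, and 842 had no symbol and stayed out as unnamed here. No column of the table was left unused.

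Groups, the limma and camera tests, gene lists, the rule for named genes and the alternatives below were fixed before the data were examined. The shuffled residuals and the exact permutation tests of macrophage, acute phase and clock genes below were chosen after results were seen. One limma model of 4 group means was fitted to all 20 arrays (R 4.3.3, limma 3.58.1, lmFit, contrasts.fit and eBayes with default settings), with 16 residual and 4.25 prior degrees of freedom and no covariate. There were 4 comparisons: EE2 minus its sunflower oil vehicle, CPZ minus its PBS vehicle, oil minus PBS, and the EE2 response minus the CPZ response. A gene was called when its two-sided p, adjusted by Benjamini-Hochberg over all genes of the comparison, was under 0.05. No paired analysis was possible because each sample number occurs in 1 group alone.

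A set of 35 gene lists for liver functions, cell types and neighbouring tissues, with 710 genes, was written from general knowledge, and 599 of these genes were measured. The lists cover bile acid synthesis, bile acid and organic ion transporters, nuclear receptors and bile acid signalling, CAR and PXR targets, AhR targets, NRF2 targets, male-biased and female-biased liver genes, estrogen-responsive genes, growth hormone and STAT5 signalling, cholesterol biosynthesis, fatty acid and triglyceride synthesis, PPARalpha and fatty acid oxidation and lipoproteins. They also cover lysosome and phospholipidosis, acute phase, coagulation, complement, interferon response, unfolded protein response, cell cycle, amino acid catabolism and urea cycle, glucose metabolism and circadian clock. The remaining lists hold pericentral and periportal hepatocyte genes and markers of macrophages, lymphocytes, neutrophils, stellate cells and fibrosis, cholangiocytes, endothelium, erythroid cells, adipocytes and pancreas. Each list was tested with camera of limma, two-sided, with its preset correlation of 0.01, adjusted over the 35 lists of a comparison and called under 0.05. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance in 1 direction without comparing them with other genes, were run as alternatives. Counts adjusted over the list alone apply Benjamini-Hochberg to the limma p-values of its members.

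Genes were named by a rule. For EE2 and for CPZ it takes the 6 largest rises and the 6 largest falls among called genes whose treated and vehicle arrays do not overlap, 11 genes fixed by name whatever their result, and up to 4 members with the smallest p as examples of a list, of which at most 3 are given. For the vehicles and for the difference of the responses it takes the 4 genes with the smallest p each way among those called, and for the difference also the 11 fixed genes. A gene named outside the rule is said to have been chosen after its values were seen. For the mean level of a list per array, exact two-sided permutation tests used all 252 assignments of 10 arrays, whose smallest p is 0.00794.

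The alternatives were quantile normalization, centring of each array on its median, leaving out the 30% of genes with the lowest mean, an intensity trend with a robust prior, array weights, sample number as a covariate, only the 10 arrays of a comparison in the model, and leaving out each array in turn. Other groupings of the arrays were drawn 100 times from 126 distinct ones, and the residuals of the 4 group means were shuffled over the 20 arrays in 100 draws, the real data included. The gene test was tested on simulated data for the EE2 comparison with 16464 genes: of 50 genes shifted by 0.5 on the log2 scale it recovered 84%, and of 50 each shifted by 1, 2 or 4 it recovered 100%, with 10 false calls among 202. The list test was tested on simulated data for the CPZ comparison, where the shifted list was recovered and 0 of 33 lists without shifted genes were called. The simulated genes were drawn independently of each other, so this could not show false list calls that correlated genes would give.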

Results

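Liver RNA was measured on 20 Affymetrix arrays from male C57BL/6 mice aged 10 weeks and weighing 21 to 27 g. The mice were gavaged for 25 days with ethinylestradiol (EE2) at 3.70 mg/kg in sunflower oil, with chlorpromazine (CPZ) at 10 mg/kg in PBS, or with the matching vehicle alone. EE2 is a synthetic estrogen and CPZ an antipsychotic drug, and both are known as causes of cholestasis, a failure of bile flow. Each of the 4 groups had 5 arrays, named here by group and by the sample number in the labels. The arrays gave 1 log2 level for each of 16464 named genes, and the number of arrays limits the precision. The labels list numbered samples and do not say that each came from a separate mouse, so the p-values measure the spread between these samples. EE2 livers stood apart from the other 15 arrays on the first principal component, which held 68.3% of the variance, and the next held 4.32%. Arrays of 1 group correlated with each other at 0.994 to 0.997 across genes. Levels below are group means ± SD over 5 arrays. Changes are differences of group means on the log2 scale with the standard error (SE) from limma, and every adjusted p for a gene is from limma over all genes. The lower quartile of all genes averaged 3.16 on the arrays without EE2 and 3.06 with EE2, and a change from or to a level near it is a lower bound.

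The first comparison asked what EE2 changed in the liver relative to sunflower oil. The largest measured rise was in Prtn3 (Entrez gene 19152), which encodes a serine protease known from neutrophils, from 4.06 ± 0.13 to 12.21 ± 0.08, a change of 8.16 (SE 0.39, 286-fold, adjusted p = 7.57e-13). The keratin genes Krt79 (Entrez gene 223917) and Krt4 (Entrez gene 16682) rose by 7.91 (SE 0.13) and 7.03 (SE 0.07). Sult3a1, a sulfotransferase gene known for female-biased expression in mouse liver, rose by 7.91 (SE 0.16), Cyp17a1, a steroidogenic P450 gene, by 7.20 (SE 0.29), and Epp13 by 7.05 (SE 0.13). With oil Krt79 stood at 3.10, Krt4 at 3.31, Sult3a1 at 2.93 and Epp13 at 3.21, near the lower quartile, so their rises are lower bounds and their rank below Prtn3 is not firm. The largest measured fall was in Hsd3b5 (Entrez gene 15496), a hydroxysteroid dehydrogenase gene typical of male liver, from 12.13 ± 0.09 to 4.05 ± 1.21, so that it fell by 8.08 on the log2 scale (SE 0.35, adjusted p = 1.08e-13). The organic anion transporter genes Slco1a1 and Slc22a7 fell by 7.28 (SE 0.23) and fell by 5.69 (SE 0.34), and Elovl3, a fatty acid elongase gene, fell by 6.64 (SE 0.20). Serpina4-ps1, named as a pseudogene, fell by 5.49 (SE 0.43), and Clec2h, a C-type lectin gene, fell by 5.36 (SE 0.19). Slc22a7 at 3.38, Elovl3 at 3.48 and Clec2h at 3.11 with EE2 lay near the lower quartile, so their falls are lower bounds too. On EE2 arrays 9, 13 and 18 Hsd3b5 stood at 3.31, 3.21 and 3.25 and Slco1a1 at 3.41, 3.60 and 3.58. On EE2 arrays 15 and 17 they stood higher, at 5.97 and 4.53 for Hsd3b5 and 5.30 and 4.24 for Slco1a1. Their falls are thus limited by low levels as well, and the order of the largest falls is not firm. For each of these 12 genes all 5 EE2 arrays lay on 1 side of all 5 oil arrays, as the rule for naming them required.

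Among bile acid genes, Cyp8b1, the sterol hydroxylase needed for cholic acid synthesis, fell by 3.91 (SE 0.21, adjusted p = 5.6e-12) from 10.75 ± 0.34 to 6.84 ± 0.47. Abcb11, the canalicular bile salt export pump, fell by 0.61 (SE 0.07, adjusted p = 9.89e-07), and Abcb4, the phospholipid transporter of the canaliculus, fell by 0.31 (SE 0.08, adjusted p = 0.0024). With sample number as a covariate the Abcb4 change was -0.19 (SE 0.07, adjusted p = 0.0397). Abcc3, which exports conjugates toward the blood, rose by 1.33 (SE 0.12, adjusted p = 8.42e-09). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 9.18 ± 0.83 with oil and 9.38 ± 0.25 with EE2, a difference of 0.21 (SE 0.30) that did not pass the test (adjusted p = 0.599). Slc10a1, the main bile acid uptake transporter, differed by -0.13 (SE 0.07, adjusted p = 0.112), Abcc2, an exporter of conjugates into bile, by -0.09 (SE 0.10, adjusted p = 0.457), and Nr0b2, which encodes the repressor SHP, by -0.51 (SE 0.24, adjusted p = 0.0892). With each array centred on its median these 3 genes passed the test, at -0.29 (adjusted p = 9.70e-04), -0.25 (adjusted p = 0.0275) and -0.68 (adjusted p = 0.0186), and Nr0b2 also did without oil array 5, at -0.69 (adjusted p = 0.0222). Of 17 measured bile acid synthesis genes 5 rose and 9 fell, with the same counts adjusted over the list alone, and Hsd3b7 fell by 1.02 (SE 0.08) and Amacr fell by 0.54 (SE 0.05). Of 21 transporter genes 6 rose and 10 fell, again with the same counts adjusted over the list alone, and Abcb1a rose by 3.08 (SE 0.15). Of 17 genes for nuclear receptors and bile acid signalling 3 rose and 9 fell (3 and 10 adjusted over the list alone), and Foxa3 fell by 1.20 (SE 0.10), Fgfr4 fell by 0.63 (SE 0.10) and Rxra fell by 0.36 (SE 0.05). As lists these 3 did not pass camera, with adjusted p = 0.222, 0.372 and 0.19. Fry, which does not compare a list with other genes, called all 3 as lower (adjusted p = 2.77e-07, 2.25e-07 and 1.74e-06), as it called most lists with EE2.

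**Figure D1:**
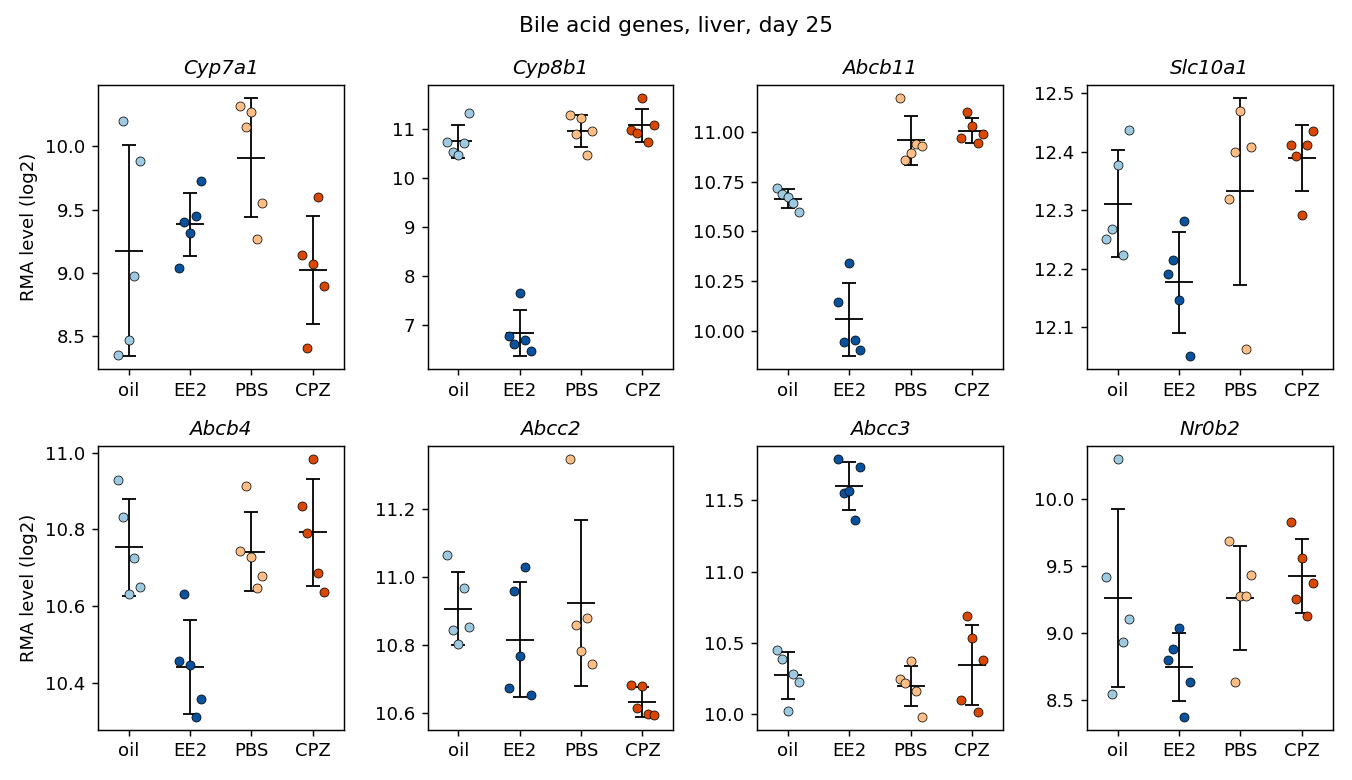
Log2 RMA level (vertical axes) of 8 bile acid genes in the 4 groups (oil, EE2, PBS, CPZ); points are arrays and bars the mean ± SD of 5 arrays. Cyp8b1 lay at 6.84 ± 0.47 on the EE2 arrays and at 10.75 ± 0.34 on the oil arrays, while Cyp7a1 overlapped between them.

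Most male-biased liver genes were lower with EE2, and more female-biased genes rose than fell. Of 20 measured male-biased liver genes 17 fell and 2 rose, with the same counts adjusted over the list alone, and the list mean was -2.58 (SD between members 2.57). Susd4 fell by 4.19 (SE 0.15), beside Slco1a1 and Elovl3, and the members that rose, chosen after their values were seen, were Cyp7b1 by 0.98, an oxysterol hydroxylase, and Scara5 by 1.06, a ferritin receptor. Of 25 female-biased genes 14 rose and 3 fell (15 and 4 adjusted over the list alone, 11 and 7 with centred arrays; mean 1.32), among them Sult1e1, the estrogen sulfotransferase, which rose by 6.25 (SE 0.22) from 2.75, a lower bound. Of 20 estrogen-responsive genes 12 rose and 3 fell (13 and 5 adjusted over the list alone; mean 1.58), with Greb1 up by 2.53 (SE 0.10) from 2.89, also a lower bound. Esr1, the estrogen receptor gene, rose by 0.56 (SE 0.11, adjusted p = 2.48e-04). Camera called all 3 lists, with adjusted p = 2.57e-10 for male-biased, 6.6e-05 for female-biased and 3.9e-05 for estrogen-responsive genes. Of the female-biased genes 7 of 25 and of the estrogen-responsive genes 7 of 20 are also in another list. These 2 lists share Cyp17a1 and Sult1e1, among others, so their calls are not independent. The male-biased and the estrogen-responsive list held with an estimated correlation (adjusted p = 0.0474 for each), and the female-biased list had adjusted p = 0.263 with an estimated correlation. Of 15 genes of growth hormone and STAT5 signalling 5 rose and 6 fell, also over the list alone, and camera did not call the list (mean 0.13, adjusted p = 0.798).

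Most macrophage and lymphocyte markers and 5 of 11 neutrophil markers were higher with EE2, though as lists they passed camera only with its preset correlation. Of 18 measured macrophage markers 14 rose and none fell, also adjusted over the list alone, by a mean of 1.02 (camera adjusted p = 9.79e-09; adjusted p = 0.239 with an estimated correlation). Csf1r, the receptor that macrophages need to survive, rose by 1.80 (SE 0.13), the Kupffer cell lectin Clec4f by 1.68 (SE 0.13) and Cd163, a scavenger receptor, by 1.79 (SE 0.16). Of 17 lymphocyte markers 13 rose and 1 fell, also over the list alone (mean 0.83, camera adjusted p = 1.65e-05; adjusted p = 0.183 with an estimated correlation). The B-cell gene Ms4a1 rose by 1.99 (SE 0.13) and the granzyme genes Gzma and Gzmb by 1.80 (SE 0.15) and 1.65 (SE 0.14). Of 11 neutrophil markers 5 rose, also over the list alone (mean 0.92, camera adjusted p = 0.00242; adjusted p = 0.263 with an estimated correlation). S100a8, an alarmin gene of neutrophils, rose by 3.88 (SE 0.31), S100a9 by 3.42 (SE 0.30) and the protease gene Mmp9 by 0.91 (SE 0.08). The neutrophil mean thus rested largely on S100a8 and S100a9. The endothelial markers, with 2 of 17 higher and 7 lower, also over the list alone, had a mean of -0.09 (camera adjusted p = 0.343).

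In the same livers most called acute phase, interferon, lysosome and cell cycle genes rose, and of these 4 lists only the lysosome list held with an estimated correlation. Of 23 acute phase genes 17 rose and 1 fell (19 and 1 adjusted over the list alone; mean 1.32, camera adjusted p = 4.12e-07; adjusted p = 0.263 with an estimated correlation). Cd14 and Lbp, which bind bacterial lipopolysaccharide, rose by 2.92 (SE 0.20) and 1.91 (SE 0.15), and Itih3 by 0.97 (SE 0.08). The member that fell was Hamp, the gene of the iron hormone hepcidin. Of 19 interferon response genes 15 rose, also over the list alone (mean 0.60, camera adjusted p = 2.83e-06; adjusted p = 0.263 with an estimated correlation). Ifit2 rose by 1.53 (SE 0.13), Oas2 by 1.44 (SE 0.16) and the RNA sensor Ddx58 by 0.74 (SE 0.07). Of 24 lysosome and phospholipidosis genes 17 rose (18 over the list alone; mean 0.33, camera adjusted p = 8.07e-07; adjusted p = 0.0474 with an estimated correlation), though with each array centred on its median 11 rose and 3 fell. Asah1, a ceramidase gene, rose by 0.89 (SE 0.08), Psap by 0.88 (SE 0.07) and the cathepsin gene Ctsb by 0.77 (SE 0.08). Of 24 cell cycle genes 18 rose and 2 fell (19 and 3 over the list alone; mean 0.45, camera adjusted p = 3.9e-05; adjusted p = 0.239 with an estimated correlation). Top2a rose by 1.63 (SE 0.14), Ccna2 by 1.37 (SE 0.13) and Mcm2 by 0.72 (SE 0.08). These rises came in the livers in which the macrophage list was higher by 1.02.

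Of 16 pericentral hepatocyte genes, expressed around the central vein, 12 fell and none rose (13 and 1 adjusted over the list alone; mean -0.54, camera adjusted p = 2.95e-04; adjusted p = 0.263 with an estimated correlation). Rhbg, an ammonium transporter, fell from 6.46 ± 0.28 to 4.97 ± 0.25, Cyp1a2 from 12.28 ± 0.05 to 10.93 ± 0.18 and Rgn from 12.70 ± 0.03 to 11.92 ± 0.15. Of 17 complement genes 11 fell and 2 rose (12 and 2 over the list alone; mean -0.45, camera adjusted p = 5.34e-04; adjusted p = 0.263 with an estimated correlation). The mannose-binding lectin Mbl1 fell by 1.60 (SE 0.08), C8a fell by 1.32 (SE 0.10) and C8g fell by 0.60 (SE 0.05). Of 17 cholesterol biosynthesis genes 10 rose and 4 fell (11 and 4 over the list alone; mean 0.39, camera adjusted p = 0.0119; adjusted p = 0.497 with an estimated correlation). Sqle, the squalene epoxidase, rose by 1.34 (SE 0.15) and the regulator Srebf2 by 0.65 (SE 0.07), and Tm7sf2, a sterol reductase, fell by 1.02 (SE 0.07). Without the genes in the lowest 30% of levels the cholesterol list had adjusted p = 0.0731. Cyp2b10, the classic target of the receptor CAR, rose by 4.36 (SE 0.25, adjusted p = 1.6e-11) with EE2, from 3.20 ± 0.28, near the lower quartile, so the rise is a lower bound. Cyp3a11, a target of PXR, differed by 0.01 (adjusted p = 0.911), which turned to -0.15 (adjusted p = 0.00554) with centred arrays. Of 18 CAR and PXR targets 9 rose and 5 fell, also over the list alone, and the list was not called (camera adjusted p = 0.295). Among them Cyp2c54 fell by 3.59 (SE 0.14) and Ces2a fell by 1.65 (SE 0.10).

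The other lists did not pass camera with EE2, and, apart from the unfolded protein response, their called members went both ways. The count that rose and the count that fell were 2 and 1 of 7 AhR targets, 8 and 6 of 18 NRF2 targets, 5 and 11 of 23 genes of fatty acid and triglyceride synthesis, 6 and 6 of 19 lipoprotein genes and 4 and 10 of 22 coagulation genes, each the same adjusted over the list alone. For these 5 lists camera gave adjusted p = 0.697, 0.12, 0.517, 0.444 and 0.275, and the NRF2 list passed with centred arrays (adjusted p = 0.0323). They were 5 and 11 of 26 genes of the PPARalpha and fatty acid oxidation list (7 and 11 over the list alone) and 6 and 6 of 21 genes of amino acid catabolism and the urea cycle (7 and 7 over the list alone), each with camera adjusted p = 0.517. Counts over the list alone equalled those over all genes for glucose metabolism (3 and 4 of 16), circadian clock (2 and 7 of 19), periportal hepatocyte (4 and 4 of 13) and stellate cell and fibrosis genes (9 and 7 of 23), with camera adjusted p = 0.909, 0.273, 0.798 and 0.275. They were also equal for cholangiocyte (4 and 3 of 14), erythroid (1 and 4 of 8), adipocyte (2 and 5 of 9) and pancreas markers (1 and 4 of 13), with camera adjusted p = 0.248, 0.295, 0.798 and 0.259. Of 23 genes of the unfolded protein response 6 rose and none fell, also over the list alone (adjusted p = 0.117), while with each array centred on its median 5 rose and 6 fell, and the list passed without oil array 2 (adjusted p = 0.0399) or EE2 array 13 (adjusted p = 0.0461). Mean, median and test differed in sign for the AhR, PPARalpha, amino acid, glucose, periportal and cholangiocyte lists. With centred arrays the means of the CAR and PXR, PPARalpha, amino acid, growth hormone, lipoprotein and stellate lists turned from positive to negative.

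In all, 7560 of 16464 genes (45.9%) passed the test with EE2, 3166 higher and 4394 lower. Of these calls 1003 of the lower and 195 of the higher ones lay in the lowest 30% of levels. With quantile normalization 7015 genes passed, and 5952 of the 7560 kept their call and direction. At least 2-fold changes were found for 616 higher and 202 lower genes, and at least 8-fold changes for 64 and 23. For 5236 genes (31.8%) the EE2 and the oil arrays did not overlap, where chance gives 0.794%. The EE2 arrays had a mean median of 4.65 against 4.50 in the other 3 groups, and centring moved the median change of all genes from -0.07 to -0.23. With centred arrays 11846 genes passed, 17.4% of them higher, against 41.9% of those called in the values as deposited, and nearly all lists had more members that fell. The count that rose and the count that fell became, for example, 12 and 2 for interferon response genes, 13 and 4 for cell cycle genes, 6 and 12 for amino acid genes and 1 and 11 for pancreas markers. Camera called 13 of the 35 lists with its preset correlation and 3 with an estimated one.

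**Figure D2:**
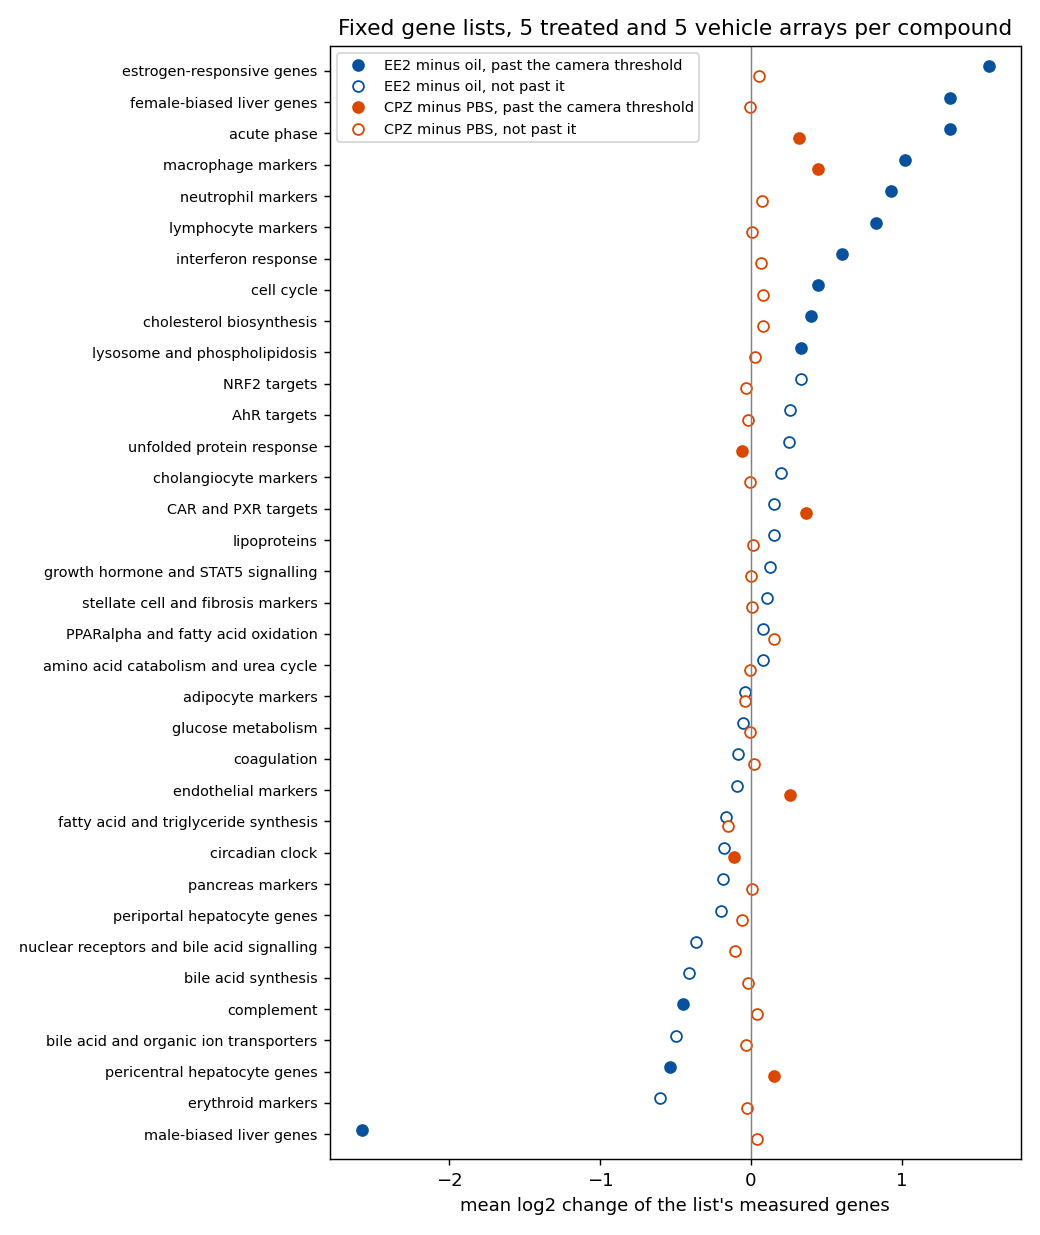
Mean log2 change (horizontal axis) of the measured genes of each of the 35 fixed lists, EE2 minus oil in blue and CPZ minus PBS in orange, 5 arrays per group; filled points passed camera with its preset correlation. Male-biased genes lay at -2.58 with EE2, and the highest CPZ list mean was 0.44, of the macrophage markers.

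The next comparison asked what CPZ changed relative to PBS. Cyp2b10 (Entrez gene 13088) rose from 4.49 ± 0.45 to 8.55 ± 0.40, a change of 4.07 (SE 0.25, 16.8-fold, adjusted p = 9.18e-09). Gadd45g, a stress-response gene, rose by 1.98 (SE 0.32, adjusted p = 0.00454), and the P450 genes Cyp2c55 and Cyp2c29 rose by 1.54 (SE 0.19, adjusted p = 6.39e-04) and 0.43 (SE 0.05, adjusted p = 8.16e-04). Lgr5, a Wnt target of pericentral hepatocytes, rose by 1.18 (SE 0.19, adjusted p = 0.00407), 1700067K01Rik by 1.14 (SE 0.18, adjusted p = 0.0049) and Acnat2, an acyltransferase gene, by 1.28 (SE 0.28, adjusted p = 0.0365). Among called genes whose arrays did not overlap, the largest falls were in Nrep, which fell by 1.21 (SE 0.25, adjusted p = 0.0216), and in Cib3, which fell by 1.21 (SE 0.26, adjusted p = 0.0341). Nmrk1, a nicotinamide riboside kinase gene, fell by 1.04, Arhgef26 fell by 1.02, Gnat1 fell by 0.85 and Clec2h fell by 0.84, with adjusted p from 0.0168 to 0.0384. All 5 CPZ arrays lay on 1 side of all 5 PBS arrays for each of these 13 genes. The rule for naming them required this of all but Cyp2c29, which was named as an example of a list.

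Of the other bile acid and receptor genes named beforehand limma called 0 with CPZ, and 3 had an unadjusted p under 0.05, Cyp7a1, Abcc2 and Esr1. Cyp7a1 stood at 9.91 ± 0.47 with PBS and 9.02 ± 0.43 with CPZ, a difference of -0.89 (SE 0.30, adjusted p = 0.201). Abcc2 differed by -0.29 (SE 0.10, adjusted p = 0.179) and Esr1 by -0.28 (SE 0.11, adjusted p = 0.278). The size of the Abcc2 difference leaned on PBS array 7, at 11.35, while the other PBS arrays lay at 10.74 to 10.88 and the CPZ arrays at 10.59 to 10.68. Differences were 0.11 for Cyp8b1, 0.05 for Abcb11, 0.06 for Slc10a1, 0.05 for Abcb4, 0.15 for Abcc3, 0.17 for Nr0b2 and -0.03 for Cyp3a11. In the bile acid synthesis list limma called 0 of 17 genes, 0 over the list alone and 2 at an unadjusted p under 0.05, with camera adjusted p = 0.844, and there the mean and the test differed in sign. In the transporter list it called 0 of 21, 0 over the list alone and 3 at an unadjusted p under 0.05, with camera adjusted p = 0.724. Of 24 lysosome and phospholipidosis genes, a list of interest because CPZ is a cationic amphiphilic drug, limma called 0, 0 over the list alone and 2 at an unadjusted p under 0.05 (mean 0.03, camera adjusted p = 0.83).

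Gene lists that passed camera with CPZ included CAR and PXR targets, of which 4 of 18 rose (6 rose and 3 fell adjusted over the list alone; mean 0.36, camera adjusted p = 3.49e-04; adjusted p = 0.186 with an estimated correlation). Of 17 endothelial markers 5 rose (9 over the list alone; mean 0.26, camera adjusted p = 8.31e-11; adjusted p = 0.133 with an estimated correlation). Stab2 rose by 0.46 (SE 0.08), Clec4g by 0.45 (SE 0.08) and Fcgr2b by 0.42 (SE 0.09), genes of the liver sinusoid. The changes with sample number as a covariate were 0.49 (SE 0.10), 0.39 (SE 0.09) and 0.39 (SE 0.10), and with these larger SE values all 3 calls ended (adjusted p = 0.0627, 0.0813 and 0.16). All 3 also ended without the 3 PBS and CPZ arrays with high Lcn2 given below (0.0729, 0.0723 and 0.17), and that of Fcgr2b without any of 4 single arrays. Of 18 macrophage markers 3 rose (13 over the list alone; mean 0.44, camera adjusted p = 1.48e-10; adjusted p = 0.23 with an estimated correlation). They were Cd68 by 0.79 (SE 0.16), C1qa by 0.64 (SE 0.12) and Adgre1 by 0.63 (SE 0.14). Their changes were no smaller with sample number as a covariate, at 0.88 (SE 0.19), 0.69 (SE 0.15) and 0.68 (SE 0.16), but all 3 calls ended (adjusted p = 0.0721, 0.0721 and 0.102). All 3 also ended with the 10 arrays alone (0.0939, 0.0555 and 0.0884) and without the 3 arrays with high Lcn2 (0.0966, 0.0541 and 0.0871). They also ended without any of 3, 1 and 6 single arrays. The PBS livers were the lowest of the 4 groups in both marker lists. The endothelial mean was 6.52 ± 0.13 with PBS, 6.77 ± 0.03 with CPZ, 6.71 ± 0.07 with oil and 6.62 ± 0.13 with EE2. The macrophage mean was 6.51 ± 0.13 with PBS, 6.96 ± 0.26 with CPZ, 6.71 ± 0.11 with oil and 7.73 ± 0.21 with EE2. Of 19 clock genes 2 fell (8 fell and 4 rose over the list alone; mean -0.11, camera adjusted p = 0.0139; adjusted p = 0.133 with an estimated correlation). They were Dbp, which fell by 0.43 (SE 0.10), and Tef, which fell by 0.30 (SE 0.06), both output genes of the clock. Dbp differed by -0.30 (SE 0.11) and Tef by -0.27 (SE 0.08) with sample number as a covariate, and both calls ended (adjusted p = 0.308 and 0.195), with smaller changes and larger SE values. Both also ended with the 10 arrays alone (0.101 and 0.0733) and without any of 8 and 7 single arrays. Per2, a clock repressor, differed by -0.49 (SE 0.12, adjusted p = 0.0531) and passed under several alternatives. These were quantile normalization (adjusted p = 0.0388), centred arrays (0.0349), the lowest 30% of genes left out (0.0417), the trend and robust prior (0.0492), array weights (0.02), and fits without PBS array 20 (0.0334), CPZ array 11 (0.00821) or the 3 arrays with high Lcn2 (0.0133). The clock list was no longer called without PBS array 10 (adjusted p = 0.0553), CPZ array 1 (adjusted p = 0.0865), CPZ array 4 (adjusted p = 0.0502) or the 3 arrays with high Lcn2 (adjusted p = 0.0621).

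Of 23 acute phase genes limma called 0 with CPZ, 5 higher over the list alone and 6 at an unadjusted p under 0.05, while camera called the list (mean 0.32, adjusted p = 0.00104; adjusted p = 0.792 with an estimated correlation). The acute phase call ended without CPZ array 1 (mean 0.16, adjusted p = 0.0865) or CPZ array 11 (mean 0.14, adjusted p = 0.135). Lcn2, a secreted acute phase protein, stood at 9.39 on PBS array 20, 10.13 on CPZ array 1 and 10.41 on CPZ array 11, and between 5.01 and 6.34 on the other PBS and CPZ arrays. Lcn2 was also high on all 5 EE2 arrays, at 9.32 to 10.75, against 4.73 to 5.86 with oil. The 3 PBS and CPZ arrays with high Lcn2 were chosen after their values were seen. Without them the list had a mean of 0.04 with CPZ (camera adjusted p = 0.666). Of 16 pericentral genes 1 rose, Lgr5, also over the list alone (mean 0.15, camera adjusted p = 0.0288; adjusted p = 0.792 with an estimated correlation). The list was not called without PBS array 19 (adjusted p = 0.421), without CPZ array 3 (adjusted p = 0.0872) or with sample number as a covariate (mean 0.08, adjusted p = 0.576). Of 23 genes of the unfolded protein response limma called 0, 2 lower over the list alone and 7 at an unadjusted p under 0.05, with camera adjusted p = 0.0417 and mean -0.06 (adjusted p = 0.792 with an estimated correlation). That call ended without PBS array 10 (adjusted p = 0.138), 19 (0.0969) or 20 (0.115), and without CPZ array 3 (0.101) or 4 (0.126). It also ended with quantile normalization (adjusted p = 0.0586), centred arrays (0.0877), the lowest 30% of genes left out (0.0755) and sample number as a covariate (mean -0.03, adjusted p = 0.0957). Genes of fatty acid and triglyceride synthesis had mean -0.15 and camera adjusted p = 0.0587, which passed without PBS array 19 (adjusted p = 0.00548), CPZ array 3 (0.00768) or CPZ array 11 (0.0236), with array weights (0.0389) and with the 10 arrays alone (0.0299). Interferon genes, with mean 0.07, passed without CPZ array 3 (mean 0.14, adjusted p = 0.00973) and with sample number as a covariate (mean 0.18, adjusted p = 0.00123). Cholesterol biosynthesis genes passed with sample number as a covariate (adjusted p = 0.0381).

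**Figure D3:**
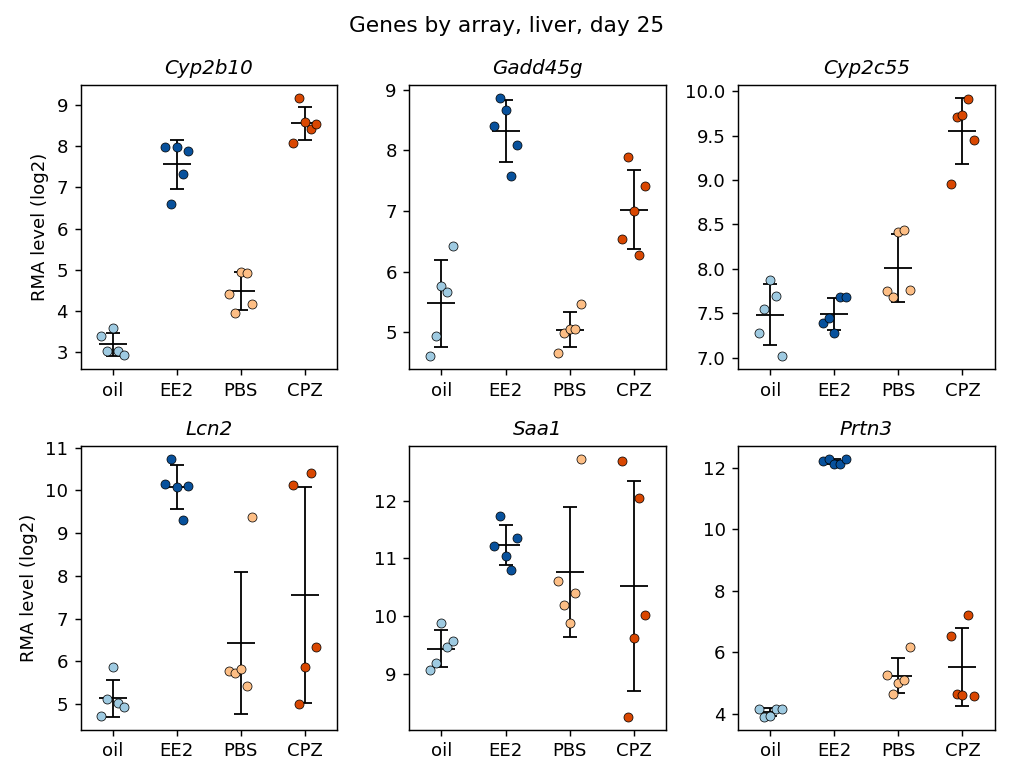
Log2 RMA level (vertical axes) of 6 genes in the 4 groups (oil, EE2, PBS, CPZ); points are arrays and bars the mean ± SD of 5 arrays. Cyp2b10 lay at 8.55 ± 0.40 on the CPZ arrays and 4.49 ± 0.45 on the PBS arrays. Lcn2 stood above 9 on all 5 EE2 arrays and, among the PBS and CPZ arrays, on PBS array 20, CPZ array 1 and CPZ array 11.

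In all, 131 of 16464 genes passed the test with CPZ, 73 higher and 58 lower, with at least 2-fold changes for 7 and 4 and a change of at least 8-fold for 1, Cyp2b10. With centred arrays 35.5% of the called genes were higher, against 55.7% in the values as deposited. For 490 genes (2.98%) the CPZ and PBS arrays did not overlap, where chance gives 0.794%. The count of called genes, 131 with all arrays, was 47 without PBS array 14, 53 without CPZ array 3, 65 without CPZ array 4 and 86 without CPZ array 1. With sample number as a covariate it was 20, all of them among the 131. The named calls it ended kept their direction, for example Nrep at -1.25 (SE 0.30) and Cib3 at -0.87 (SE 0.28). Of the 21 named genes past the threshold, leaving out 1 array ended 13 calls without PBS array 14, 9 without CPZ array 3 or 4, 7 without PBS array 7 or CPZ array 1, 6 without PBS array 19, 5 without PBS array 10 or CPZ array 12, 4 without PBS array 20 and 3 without CPZ array 11. Cyp2b10, Gadd45g, Cyp2c55, Cyp2c29 and 1700067K01Rik kept their call under every alternative, and Lgr5 lost it with sample number as a covariate (0.89, SE 0.19, adjusted p = 0.0721).

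The 2 vehicles were compared as the background of both treatments, oil minus PBS. Cry2 and Cry1, repressors of the circadian clock, were higher with oil by 0.42 (SE 0.07, adjusted p = 0.0185) and 0.58 (SE 0.10, adjusted p = 0.0406), and the collagen gene Col27a1 by 0.77 (SE 0.14, adjusted p = 0.0406). Lower with oil were Trim2 by a change of -0.37 (SE 0.05, adjusted p = 0.00242), Aldh1b1, an aldehyde dehydrogenase gene, by -1.06 (SE 0.15, adjusted p = 0.0046), Ube2u by -0.70 (SE 0.11, adjusted p = 0.00937) and Atp6v0d2, a proton pump gene, by -0.92 (SE 0.15, adjusted p = 0.0234). These 7 genes and Zbtb45 (-0.38, named after its value was seen) were the 8 of 16464 that passed, and for all 8 the groups did not overlap. Cyp2b10 stood at 3.20 ± 0.28 with oil and 4.49 ± 0.45 with PBS, a difference of -1.29 (SE 0.25, adjusted p = 0.0672). The count of 8 became 2 without PBS array 14, 19 without PBS array 19, 3 without oil array 5 or 8, 4 without oil array 2 or 6 or PBS array 20, and 2 with sample number as a covariate. With the 10 vehicle arrays alone limma called 0 genes, while 1337 had an unadjusted p under 0.05, and Trim2 had adjusted p = 0.0653. Of the 7 named calls 5 ended without PBS array 14, 4 without oil array 5 or 8, 3 without oil array 2 or 6 or PBS array 20, 2 without PBS array 19 and 1 without oil array 16 or PBS array 10.

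Camera called 10 lists between the vehicles, and with an estimated correlation it called 0, with 5 at an unadjusted p under 0.05. Endothelial markers were higher with oil by a mean of 0.20 (adjusted p = 9.36e-09; adjusted p = 0.172 with an estimated correlation) and macrophage markers by 0.20 (adjusted p = 8.94e-04; adjusted p = 0.772 with an estimated correlation). Of 19 clock genes 2 were higher, Cry1 and Cry2 (3 over the list alone; mean 0.13, adjusted p = 0.00148; adjusted p = 0.0961 with an estimated correlation). The mean was 0.17 for PPARalpha and fatty acid oxidation (adjusted p = 0.315 with an estimated correlation; mean 0.10 without PBS array 20 and 0.08 with sample number as a covariate) and 0.15 for cell cycle genes (adjusted p = 0.27 with an estimated correlation). It was -0.21 for CAR and PXR targets and -0.12 for amino acid genes, each with adjusted p = 0.27 with an estimated correlation. For fatty acid synthesis (-0.16), interferon response (-0.13) and acute phase genes (-0.44) adjusted p = 0.772 with an estimated correlation. The acute phase call ended without PBS array 20 (mean -0.27, adjusted p = 0.272, but 0.0182 with CPZ arrays 1 and 11 also left out) and with sample number as a covariate (mean -0.35, adjusted p = 0.052). The covariate also ended the interferon (mean -0.04, adjusted p = 0.489) and fatty acid synthesis (mean -0.08, adjusted p = 0.333) calls, and the fatty acid synthesis call also ended without PBS array 7 (0.0565), PBS array 14 (0.0569) or oil array 8 (0.069).

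The last comparison set the EE2 response, relative to oil, against the CPZ response, relative to PBS, as a test of the difference itself. The change of keratin genes was higher with EE2, by 8.02 (SE 0.19) for Krt79 and 7.12 (SE 0.10) for Krt4, both lower bounds, as it was for Rgs7bp by 6.97 (SE 0.13) and the metalloprotease gene Adam19 by 4.66 (SE 0.11). The difference was -7.38 (SE 0.29) for Elovl3, -7.27 (SE 0.33) for Slco1a1, -4.24 (SE 0.19) for Cyp2c54 and -4.18 (SE 0.20) for Adh6-ps1. For Elovl3 and Slco1a1 it is limited by their low levels with EE2. The responses differed for Cyp8b1 by -4.02 (adjusted p = 2.53e-09), Abcb11 by -0.65 (adjusted p = 6.36e-05), Abcc3 by 1.18 (adjusted p = 1.27e-05) and Esr1 by 0.84 (adjusted p = 2.52e-04). The Abcb4 difference of -0.36 (adjusted p = 0.0153) was not called with quantile normalization (adjusted p = 0.0523) or with sample number as a covariate (-0.11, SE 0.12, adjusted p = 0.559). Cyp2b10, which rose with both compounds, differed by 0.30 (SE 0.36, adjusted p = 0.558), a value limited by its low level with oil. Not past the threshold were Nr0b2 at -0.68 (adjusted p = 0.14), Abcc2 at 0.20 (adjusted p = 0.281), Cyp3a11 at 0.03 (SE 0.06) and Slc10a1 at -0.19 (adjusted p = 0.14), which passed with centred arrays at -0.33 (adjusted p = 0.00965). Cyp7a1, at 1.10 (SE 0.43, adjusted p = 0.0582), passed without oil array 5 (adjusted p = 0.0124), oil array 16 (0.0287), PBS array 19 (0.0331) or CPZ array 11 (0.0354), with array weights (0.0436), without the 3 arrays with high Lcn2 (0.0338) and with the lowest 30% of genes left out (0.05, below the threshold before rounding).

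In all, 5209 genes differed in response, 2404 with a higher and 2805 with a lower change under EE2 than under CPZ. With centred arrays 20.3% of the called genes were the higher ones, against 46.2% in the values as deposited. With sample number as a covariate the count was 3048, of which 2894 were among the 5209. Camera called 15 lists, of which the male-biased genes (mean -2.62) and the estrogen-responsive genes (mean 1.52) held with an estimated correlation, each at adjusted p = 0.0397. Endothelial markers differed by -0.35 (adjusted p = 0.0026; adjusted p = 0.358 with an estimated correlation) and macrophage markers by 0.57 (adjusted p = 1.99e-05; adjusted p = 0.358 with an estimated correlation). Lysosome genes differed by 0.31 (adjusted p = 6.63e-06; adjusted p = 0.0664 with an estimated correlation). Of the 131 genes called with CPZ 98 were also called with EE2, 69 in the same direction and 29 in the opposite one. There were 33 genes higher with both, where independence gives 14.0, and 36 lower with both, where it gives 15.5. Across all 16464 genes, which are not independent replicates, the responses correlated with Pearson's r 0.175 and Spearman's rho 0.0869, and r was 0.0753 without CPZ array 11 and 0.0519 without the 3 arrays with high Lcn2.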

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

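The test of shuffled residuals, the test of macrophage against endothelial markers, both tests of the acute phase genes and the test of the clock genes by time of day were chosen after their results were seen; the other tests in this part were written down before.

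Single arrays stood apart from the other 4 of their group in 9 of 236 groups of gene values and 9 of 140 groups of list means, by the gap to the nearest array relative to the range; chance does this in about 1 in 20 groups, or 11.8 and 7 here. Krt4 stood at 3.20 on oil array 16, where the others lay at 3.32 to 3.36. Fgfr4 stood at 4.80 on oil array 5 (others 5.15 to 5.25), and Ms4a1 at 4.12 on oil array 8 (others 3.74 to 3.82). On EE2 array 15 Cyp8b1 stood at 7.66 (others 6.46 to 6.77) and Abcb1a at 6.75 (others 7.36 to 7.59). On PBS array 7 Abcb11 stood at 11.17 (others 10.86 to 10.94) and Abcc2 at 11.35 (others 10.74 to 10.88), and on PBS array 10 Gnat1 stood at 6.15 (others 6.49 to 6.62). Dbp stood at 10.51 on CPZ array 11 (others 10.04 to 10.13).

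Among list means, oil array 6 stood apart in 4 lists: acute phase genes at 9.30 (others 9.08 to 9.12), pericentral genes at 8.65 (others 8.81 to 8.87), cholangiocyte markers at 5.01 (others 4.89 to 4.92) and pancreas markers at 3.75 (others 3.60 to 3.63). On EE2 array 9 the pericentral mean was 8.41 (others 8.22 to 8.23). On PBS array 7 the lipoprotein mean was 11.48 (others 11.45 to 11.46), and on PBS array 19 the periportal mean was 10.94 (others 10.65 to 10.73). On PBS array 20 the acute phase mean was 10.27 (others 9.40 to 9.44) and the neutrophil mean 4.41 (others 3.85 to 3.94). Among the 842 unnamed probe sets, which are outside the comparisons of genes, limma called 361 with EE2, 148 higher and 213 lower, and 5 with CPZ, against 0 between the vehicles (74 at an unadjusted p under 0.05).

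Chance as the source of the gene counts was tested with 100 groupings of the arrays. For EE2 only the real grouping, or 1 of 100, gave as many as 7560 genes, and the highest other count was 578; for CPZ it was 1 of 100 with 131 genes and a highest other count of 3. Between the vehicles 2 of 100 gave as many as 8, and the highest other count was 12. For the difference of the responses it was 1 of 100 with 5209 genes and a highest other count of 3, though exchanging arrays mixes very different livers there and in the EE2 comparison, which widens the spread within groups. A further test therefore kept that spread by shuffling the residuals of the group means over the 20 arrays, in 100 draws with the real data included. Only the real data, 1 of 100, gave as many genes in each comparison, and the highest other counts were 3 for EE2, 1 for CPZ, 4 for the vehicles and 1 for the difference of the responses. The shuffled residuals thus argue against chance for EE2, CPZ and the difference, as the groupings do for CPZ. In each case 1 of 100 is the smallest share that the test can give. For the vehicles both tests also argue against chance, but the count of 8 is not firm, since 1 other grouping gave 12, single arrays left out gave 2 to 19 and the 10 vehicle arrays alone gave 0 (1337 at an unadjusted p under 0.05).

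With EE2 the macrophage list was higher by 1.02, the lymphocyte list by 0.83 and the neutrophil list by 0.92. The neutrophil mean rested largely on S100a8 and S100a9, while Mpo and Elane of that list did not pass the limma test. A lower share of hepatocytes alone would raise the markers of every other cell type alike. Yet the macrophage list rose more than the endothelial list by 1.11 in an exact permutation test (p = 0.00794, the smallest it can give). The lists were compared after their means were seen, so the p adds little to those means. The values argue against a lower share of hepatocytes as the whole source, provided that endothelial genes did not fall for another reason. The wider distribution of values on the EE2 arrays was also argued against, since the macrophage mean was 1.00 after quantile normalization. Of the 18 macrophage markers 1 is in another list and 12 lie above the median gene in vehicle livers, against 7 of 17 lymphocyte and 3 of 11 neutrophil markers. A candidate explanation left open is more immune cells in these livers, or higher levels of these genes per cell, and whole liver RNA does not part the 2.

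With CPZ the acute phase list was called by camera with a mean of 0.32 (adjusted p = 0.00104, but adjusted p = 0.792 with an estimated correlation), while Saa1 stood at 12.72 on PBS array 20, 12.68 on CPZ array 1 and 12.04 on CPZ array 11. A common rise in all CPZ arrays could not be shown, with an exact permutation p = 0.262 for the list mean per array, and 1 of 5 CPZ arrays, CPZ array 3, lay at or below the vehicle median. Single animals with a strong acute phase in both groups would widen the spread, and the SD between arrays was 3.39 times that in EE2 and its vehicle. The ratio itself was not tested. An exact permutation test over the 20 arrays compared the mean absolute deviations from the group medians instead and gave p = 0.108. These explanations cannot be told apart with 5 arrays per group, and either may hold.

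Clock genes differed between CPZ and its vehicle in opposite ways: the 5 genes that peak with Arntl and the 9 that peak with Dbp moved apart by 0.65 (SE 0.13). With sample number as a covariate the gap was 0.56 (SE 0.15), above the bound of 0.33 set beforehand, which argues against a drift with sample number as the whole source. A different time of day at sampling would move these genes apart, and an exact permutation test of the gap gave p = 0.00794, the smallest it can give (adjusted p = 0.0238 over 3 contrasts), against 0.00 for EE2 (exact p = 0.984) and 0.07 between the vehicles (exact p = 0.675). A different time of day may thus contribute; the time of sampling is not given in the sources used here, and an effect of CPZ on the clock itself stays open, as untested.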

How the results depend on the processing

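Leaving out the 3 PBS and CPZ arrays with high Lcn2 together was chosen after the data were seen. The other alternatives were planned, and the cause of a change was not tested unless stated. Over all alternatives 281 counts stayed within 1.5 times their value and 74 did not. Of the list results 1916 kept their call and direction, 88 lost the call, 24 gained one and 1 reversed, and of the named genes 2464, 144, 28 and 1. These list results cover every list for EE2 and CPZ. For the vehicles and the difference they cover only the lists that camera called with its preset correlation, so calls gained there are not counted. All 59 named EE2 calls held under every alternative, as did 5 of 21 for CPZ, 0 of 7 between the vehicles and 12 of 13 for the difference. With centred arrays the EE2 count was 11846 and that of the difference 8194, which follows from moving all genes of an array by 1 value, and Cyp3a11 with EE2 turned to -0.15. With sample number as a covariate the counts were 20 for CPZ, 2 for the vehicles and 3048 for the difference; sample numbers are partly collinear with group, since CPZ has 1, 3, 4, 11 and 12 and its vehicle 7, 10, 14, 19 and 20. CPZ gave 237 genes with array weights and 64 with its 10 arrays alone, and the vehicles gave 13 with the trend and robust prior and 0 with their 10 arrays alone (1337 at an unadjusted p under 0.05), where fewer arrays estimate the spread. Leaving out each array in turn gave 6885 to 7246 genes for EE2, 47 to 148 for CPZ, 2 to 19 for the vehicles and 4730 to 5264 for the difference, and 0.0753 to 0.205 for the correlation of the responses across genes. Without the 3 arrays with high Lcn2 the counts were 7541, 104, 9 and 4773 and the correlation 0.0519. Called lists numbered 13, 7, 10 and 15 for EE2, CPZ, the vehicles and the difference; with an estimated correlation 3, 0, 0 and 2, where 4 and 5 had an unadjusted p under 0.05 in place of the counts of 0; with fry 27, 4, 1 and 26; with each array left out 13 to 14, 5 to 7, 9 to 12 and 14 to 15. The adipocyte list with EE2 (mean -0.0414) turned direction with fry. The planned mean over probe sets of a gene changed nothing, since each gene has 1 probe set, and has no value. Signal near background limits how far a fall to it or a rise from it can be measured. With EE2 1003 of the lower and 195 of the higher calls lay in the lowest 30% of levels. The lower quartile averaged 3.06 with EE2 and 3.16 in the other groups, so part of these low-level calls may follow that shift, which was not tested.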

Other observations

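The genes in this part were chosen after their values were seen, and no explanation was tested for them. Prtn3, the neutrophil protease gene with the largest measured EE2 rise (8.16, SE 0.39), rose while Mpo and Elane, granule genes of the neutrophil list, did not pass the limma test. Mpo differed by -0.09 (SE 0.07, adjusted p = 0.291) and Elane by 0.05 (SE 0.10, adjusted p = 0.715), and on the EE2 arrays they stood at 3.28 ± 0.10 and 3.89 ± 0.11. Several lists that camera did not call with EE2 held large opposite changes. In growth hormone signalling Stat5a rose by 2.43 (SE 0.12) and Socs2, a feedback inhibitor, by 2.22 (SE 0.35), whereas Igfbp2 fell by 2.34 (SE 0.12) and the hepatocyte factor Onecut1 fell by 2.68 (SE 0.52). Among adipocyte markers Fabp4 rose by 5.00 (SE 0.10), from 7.66 ± 0.09 to 12.67 ± 0.15, and Car3 fell by 4.87 (SE 0.34). The trefoil gene Tff3 rose by 5.09 (SE 0.51) with EE2 and differed by -2.02 (SE 0.51, adjusted p = 0.0656) with CPZ. Of the biliary keratins Krt7 differed by 0.18 (adjusted p = 0.0939) and Krt19 by -0.13 (adjusted p = 0.249) with EE2.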
